A study of Mus musculus with 2 samples.

How the data were processed

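The data were ChIP-seq peak lists for H3K4me3, a histone methylation found at promoters of active genes and of many developmental genes held ready for use, in stomach dissected from mouse embryos of the B6NCrl strain at embryonic day 15.5. Per the labels, the 2 biological replicates were separate pools of tissue, from 78 embryos for replicate 1 and 62 for replicate 2, with males and females mixed in each pool. The library fragments were selected between 300 and 500 bp, per the labels.

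Each replicate came with its own peak list. A pooled list was called on the alignments of both replicates, and a replicated list was derived from the pooled and the per-replicate lists, per the file headers. Each list was made against a control library and is in mm10 coordinates, per the file headers. The aligner, the peak caller, its thresholds and the rule for keeping a peak as replicated are not given in the sources used here. In the lists, the fold enrichment over control is the authors' own value for each peak, deposited as a ratio, and it was used only to describe, rank or filter peaks within a list. The deposited significance of each peak is on the −log10 scale, as a p-value and as a q-value by the authors' caller. The smallest deposited −log10 p was 2.00 in replicate 1, 2.01 in replicate 2 and the pooled list and 2.16 in the replicated list, so the calls reach weak peaks. Read numbers are not part of the peak lists, so the depth of each replicate is unknown, and intervals below cover counting error over genes or peaks only.

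Peak starts were converted to count from 1. Gene records, transcript 5' ends and exons were taken from GENCODE M21, and chromosome lengths and the CpG observed to expected ratio of promoters from GRCm38.p6, the build that mm10 names. The promoter of a gene was the window of 1000 bp on each side of the 5' end of its gene record. There were 21911 protein-coding genes with distinct symbols on the 21 assembled chromosomes. The 22 gene lists held 402 different genes, and 1 symbol was matched through a synonym (Cblif, named Gif in the annotation). Peaks with gaps of up to 500 bp were merged into regions, and the widest region that overlapped a promoter was taken as the region of that gene.

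The share of peaks of one replicate that overlapped a peak of the other by at least 1 bp was set against 100 random placements of the second list on the same chromosomes, in a one-sided permutation test whose smallest possible p is 0.0099. Pooled peaks with and without replication were compared with Fisher's exact test, two-sided. Shares have exact Clopper-Pearson intervals at 95% confidence. For each gene list, the share of members with a promoter peak was compared with that of the other protein-coding genes by Fisher's exact test, two-sided. The median region width of its occupied members was compared with 10000 random lists of the same size drawn from genes with a promoter peak, in a two-sided permutation test whose smallest possible p is 0.0002. Both families were adjusted by the Benjamini-Hochberg method over the lists, at a threshold of 0.05, and lists with fewer than 5 occupied members had no width test. Genes and peaks are units of counting here and not biological replicates. The design has 1 tissue and 1 stage, so no test between conditions was possible, and values are given for each replicate or as mean ± SD over the 2 replicates.

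The gene lists, the tests, the windows, the rule for named genes and most alternatives were fixed before the data were examined. By that rule the text names, from each list, the 2 members with the widest promoter region and the first 2 in list order without a peak, or all members where at most 4 had or lacked one. It also names the 10 widest promoter regions, the 5 promoter peaks of highest enrichment, the 5 peaks of highest enrichment more than 10000 bp from any 5' end, and the Hox genes at the borders of marked stretches. Alternatives were a reciprocal overlap of 50%, summits within 200 bp, a −log10 q of at least 10, windows of 500 and 2500 bp, 5' ends of all transcripts, the pooled list, each replicate's list alone, no merging and merging over gaps of up to 1000 bp, classing a peak by any overlap with a promoter, and random lists matched on the decile of CpG ratio (10 classes). Widths with each region counted once, widths with all transcripts' 5' ends, position classes in the pooled list, region enrichment against CpG-matched lists and olfactory receptor genes as a class were added after the data were seen.

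The list tests were tested on simulated data. Among 1100 random lists given 95% occupancy, 78.7% were called, against 1.82% of 1100 random lists with no effect, over 21911 genes. Lists with region widths multiplied by 1.5 were called in 75.8% of 120 cases and by 2 in 100% of 120, against 3% of 200 lists with no effect, over 14026 genes with a promoter region. The simulated width lists had the full list sizes, so the rates may be lower for real lists with few occupied members. The lists with no effect were independent random draws, as in the test itself. Lists of neighbouring genes and lists of low occupancy were not simulated. Overlap and merging functions gave the same counts as bedtools 2.31.1. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and random draws used seed 1.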

Results

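H3K4me3 was mapped by ChIP-seq in whole stomach of mouse embryos at day 15.5, in 2 biological replicates that each pooled many embryos. There was 1 group and no contrasting tissue, stage or treatment. The comparisons are therefore between the replicates, between peaks that did and did not replicate, and between groups of genes within the tissue. Replicate 1 had 31642 peaks over 38.0 Mb and replicate 2 had 31737 peaks over 33.7 Mb, with median widths of 847 and 730.0 bp. The pooled list had 32799 peaks over 40.1 Mb, and the replicated list 24042 peaks over 37.8 Mb, 1.43% of the sequenced bases of the chromosomes. Sequencing depth is unknown. A single interval was identical in both replicates.

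The replicates shared most of their marked sequence. Of the peaks of replicate 1, 75.9% (95% interval 75.4 to 76.4) overlapped a peak of replicate 2, and 84.8% (84.4 to 85.2) of those of replicate 2 overlapped one of replicate 1. Random placement gave means of 2.90% and 2.92%, and no placement reached the observed share (one-sided permutation p = 0.0099 in each direction, the smallest that 100 placements can give). Placement was uniform along each chromosome, whereas the mark gathers at promoters. The p-value thus shows only more overlap than uniform placement gives and adds little support for agreement of the replicates. Of the bases covered in either replicate, 31.4 Mb of 40.3 Mb were covered in both, a Jaccard index of 0.781. The 7622 peaks found in replicate 1 alone had a median width of 242 bp and a median enrichment of 3.04-fold over control, against 1337 bp and 19.6-fold for its shared peaks. Likewise the 4813 peaks of replicate 2 alone had medians of 206 bp and 2.97-fold, against 1009 bp and 12.2-fold for its shared peaks.

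Peaks at 5' ends of genes made up most of the replicated list and few of the peaks left out of it. Of the 32799 pooled peaks, 24042 (73.3%, interval 72.8 to 73.8) were in the replicated list. The summit lay within 1000 bp of the 5' end of a gene record in 13838 of these (57.6%), against 1254 of the 8757 others (14.3%), an odds ratio of 8.11. The median width was 1400.0 bp for replicated and 238 bp for other pooled peaks, and the median enrichment 19.6-fold and 2.58-fold. Peaks narrower than 500 bp were 15.8% of the replicated and 97.4% of the other peaks, and 2 of the 8757 others reached an enrichment of 5-fold, against 18507 of the replicated peaks. The p-values of these 3 Fisher's exact tests were too small to be represented in double precision. Each replicated peak was identical to a pooled peak, and 95.7% overlapped a peak in both replicates, against 0.925% of the other pooled peaks. The split thus followed which peaks were called in each replicate. Differences in width and enrichment were therefore largely built into it, and the p-values of these tests add no support.

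H3K4me3 lay mainly at gene starts and was widest and strongest there. Of the 24031 replicated peaks on assembled chromosomes, 57.6% (interval 57.0 to 58.2) had their summit within 1000 bp of a 5' end, 11.0% in an exon, 18.1% in an intron and 13.2% between genes. Only the 5' ends of gene records counted here, so a peak at another transcript's start could be classed as exon or intron. Median widths were 1878 bp at 5' ends, 1112 bp in exons, 636 bp in introns and 648 bp between genes, and median enrichments were 36.5, 10.2, 4.61 and 5.67-fold. In the replicates' own lists the share at 5' ends was 48.0% ± 0.908 (SD, n = 2), lower than in the replicated list by more than the spread between replicates. Protein-coding genes were nearest to 84.8% of the peaks at 5' ends, lincRNA genes to 3.64% and antisense genes to 4.36%. Peak density differed between chromosomes. Chromosome 11 had the most replicated peaks per Mb, 15.9, and chromosome 14 the fewest of the autosomes, 6.38. Chromosome X had 4.21 and chromosome Y 0.0654 per Mb. In replicate 1 chromosome 11 had 21.4 and in replicate 2 22.2 peaks per Mb.

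Among 21911 protein-coding genes, 14026 (64.0%, interval 63.4 to 64.6) carried a replicated promoter peak. Each replicate's own list gave nearly that share, 64.5% ± 0.549 (SD, n = 2). Occupancy followed the CpG content of the promoter: it was 1.09% in the lowest decile of the CpG observed to expected ratio, 44.4% in the fourth lowest, 83.2% in the decile above it and 99.7% in the highest. Extending promoters to the 5' ends of all transcripts raised the share to 67.6%.

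Transcription factor genes of the foregut and gastric epithelium were marked almost throughout. A promoter peak lay at 19 of 20 members (95%, interval 75.1 to 99.9), against 64.0% of other genes (Fisher's exact test, adjusted p = 0.0065). Foxa1, a pioneer factor of endodermal epithelia, had a region of 10266 bp (8519 ± 2530 in the replicates, SD, n = 2) and Gata6, an endodermal zinc finger factor, one of 9974 bp (9303.5 ± 829). Trp63, the factor of stratified epithelia, was the member without a peak at the 5' end of its gene record, although another of its transcripts started at a peak. Epithelial adhesion and keratin genes were marked in 22 of 24 cases (91.7%, adjusted p = 0.0109, exact test), among them the epithelial splicing regulators Esrp1 (5337 bp, replicates 5227.5 ± 119.5) and Esrp2 (5207 bp, replicates 5178 ± 457). Krt14 had no peak, and Krt19 had one only at another transcript. Both lists also lay above random lists of equal CpG content, whose medians were 70.0% and 70.8% (permutation test, adjusted p = 0.0077 for each).

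By contrast, genes for the products of the mature stomach were mostly unmarked. In the list of gastric secretory products 3 of 20 members (15.0%, interval 3.21 to 37.9) had a promoter peak, fewer than among other genes (adjusted p = 0.0002, Fisher's exact test). These were Muc1, a membrane mucin (6535 bp, replicates 4385 ± 2201), Bhlha15, a transcription factor of secretory cells (2615 bp, replicates 2522 ± 225), and Aqp5, a water channel (1061 bp, replicates 1037 ± 147). The region of Muc1 also covered the 5' end of its neighbour Mtx1 and was 3587 bp wide without merging. Gif, the gene of gastric intrinsic factor, and Pgc, that of pepsinogen C, had no peak in any of the 4 lists. Promoters in this list were poor in CpG, and CpG-matched random lists had a median of 25% (permutation test, adjusted p = 0.62).

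The gastric mesenchyme list was marked in 24 of 25 members (96.0%, interval 79.6 to 99.9, adjusted p = 0.0015, Fisher's exact test). It held the widest promoter region of the genome after merging over gaps of up to 500 bp. That region, at the Hedgehog receptor gene Ptch1, spanned 18286 bp on chromosome 13 from 63555807 to 63574092, of which 494 bp lay upstream of the gene, 1262 bp in its exons and 16530 bp in its introns. The width at Ptch1 depended on the replicate. It was 18271 bp in replicate 1 and 3627 bp in replicate 2, where unmarked gaps divided the same stretch, and 2526 bp in the replicated list without merging. The rank of Ptch1 depended on merging too. With gaps of up to 1000 bp closed it had 21406 bp, less than the 24798 bp of Hoxa1 and Hoxa2. Without merging it lay below Meis1 (14386 bp). With gaps of up to 500 bp closed Meis2, a homeobox gene, followed with 17206 bp on chromosome 2 from 116055801 to 116073006 (replicates 15311 ± 3705). Hand1, a basic helix-loop-helix factor gene, was the member without a replicated peak, and each replicate's own list had one there, of 598 bp in replicate 1 and 185 bp in replicate 2. The list's share equalled that of CpG-matched random lists, whose median was 96.0% (permutation test, adjusted p = 1).

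Most marker genes of the other cell types of the stomach wall were marked too. For smooth muscle and interstitial cells of Cajal, the pacemaker cells of the gut, 14 of 16 members had a peak (87.5%, adjusted p = 0.0866, Fisher's exact test), with the widest regions at Smtn (4909 bp, replicates 4878.5 ± 71.4) and Srf (4711 bp, replicates 4330.5 ± 101.1). Kcnmb1 had no replicated peak, and Ano1, a chloride channel of interstitial cells of Cajal, had one only at another transcript. Enteric neurons and glia were marked at 18 of 20 genes (90.0%, adjusted p = 0.0324, exact test), led by Hand2 (11807 bp, replicates 11835 ± 864, 5921 bp without merging) and Gfra1, a receptor of the glial factor GDNF (5169 bp, replicates 4622 ± 724). The glial genes Plp1 and S100b had no peak. This call was lost with windows of 500 bp (16 of 20, adjusted p = 0.24, exact test), in replicate 2's list alone (17 of 20, adjusted p = 0.0867, exact test) and among CpG-matched lists (adjusted p = 0.60, permutation test). Endothelial genes had peaks in 15 of 18 cases (83.3%, adjusted p = 0.15, exact test), with Lyl1 (7210 bp, a region that runs into Nfix, replicates 4544.5 ± 3774) and Tal1 (4914 bp, replicates 3509.5 ± 1709) widest, none at Emcn, and peaks only at other transcripts of Pecam1 and Egfl7. Mesothelial genes had them in 9 of 10 (adjusted p = 0.12, exact test), with 6051 bp at Wt1 and 3475 bp at Bnc2, and none at Gpm6a. In replicate 2 Lyl1 had 1876 bp and Tal1 2301 bp, so their order turned. At a −log10 q of at least 10 the mesothelial share was 6 of 10, below that of other genes (adjusted p = 1, exact test). Smooth muscle was called higher in the pooled list and with all transcripts (each 15 of 16, adjusted p = 0.030 and 0.043, exact test). Endothelium was called higher with all transcripts (17 of 18, adjusted p = 0.019, exact test). CpG-matched lists had medians of 62.5% for smooth muscle, 61.1% for endothelium and 70% for mesothelium. None of these lists was called against them (adjusted p = 0.0502, 0.098 and 0.098, permutation test).

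Blood cell genes were marked less often than other genes, at 4 of 18 members (22.2%, interval 6.41 to 47.6, adjusted p = 0.0016, Fisher's exact test). The 4 were Ikzf1 (2363 bp), Klf1 (2026 bp), Runx1 (1619 bp, 7258 bp with all transcripts) and Gfi1b (1242 bp, 729 bp without merging), genes of factors of blood development. Ptprc, the common leukocyte antigen gene, had no replicated peak, and Spi1 had one only at another transcript. In the pooled list 50% of the members had a peak, which was not called (adjusted p = 0.22, exact test), and CpG-matched lists had a median of 27.8% (adjusted p = 1, permutation test).

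Marker genes of other organs were marked less uniformly. Liver genes had a peak in 4 of 16 cases (25%, adjusted p = 0.0069, Fisher's exact test), at Prox1 (3426 bp), Apoh (3050 bp), Ttr (1493 bp, but 1616 bp in replicate 1 and 344 bp in replicate 2) and Trf (903 bp), whereas Alb and Afp, the albumin and alpha-fetoprotein genes, had none. The region of Apoh also covered the 5' end of Prkca. Germ cell genes had one in 3 of 18 cases (16.7%, adjusted p = 0.00057, exact test), at Gdf9 (2162 bp, a region that also covered the 5' end of Uqcrq), Dazl (769 bp) and Tdrd1 (573 bp), and none at Ddx4 and Sycp1. With windows of 2500 bp it was 5 of 18 (adjusted p = 0.0053, exact test). Their CpG-matched random lists had medians of 37.5% and 61.1%, and against these the germ cell list remained lower (adjusted p = 0.0022, permutation test) and the liver list was not called (adjusted p = 0.60, permutation test). The intestinal list had 8 of 18, with Cdx2 (3770 bp) and Lgr5 (2819 bp) widest and none at Lct and Alpi (adjusted p = 0.11, exact test), and 5 of 18 at a −log10 q of at least 10 (adjusted p = 0.011, exact test). For the pancreas it was 11 of 19, with Nkx6-1 (4614 bp) and Pdx1 (3677 bp, 7403 bp in the pooled list) widest and none at the insulin genes Ins1 and Ins2 (adjusted p = 0.67, exact test). The lung and thyroid list had 5 of 14, with Foxe1 (3497 bp) and Etv5 (2877 bp, 1714 bp without merging) widest and none at Sftpa1 and Sftpb. The skeletal and cardiac muscle list had 7 of 18, with Actn3 (2173 bp, a region that also covered the 5' end of Zdhhc24) and Ryr2 (2011 bp) widest and none at Myog and Myf5 (adjusted p = 0.0682 for both lists, exact test). Muscle was called lower with windows of 500 bp and at a −log10 q of at least 10 (adjusted p = 0.026 and 0.011, exact test). It was also lower in the pooled list and replicate 1's list (adjusted p = 0.035 and 0.021, exact test). Lung and thyroid was called lower at that q and in the pooled list (adjusted p = 0.019 and 0.035, exact test). Neither was called among CpG-matched lists (adjusted p = 0.24 for muscle and 0.74 for lung and thyroid, permutation test). Among transcription factor genes of the central nervous system, 18 of 21 had a peak (85.7%, adjusted p = 0.0682, exact test), with 4521 bp at Dlx1 and 4278 bp at Dlx2 (1989 bp without merging), and the others, Otx2, Tbr1 and Six3, had one at another transcript. This list was called higher with windows of 2500 bp (19 of 21, adjusted p = 0.035, exact test) and with all transcripts (21 of 21, adjusted p = 0.0015, exact test). It was also called in the pooled list and in replicate 2's list alone (adjusted p = 0.030 and 0.027, exact test), but in no other alternative. CpG-matched lists had a median of 95.2% (adjusted p = 0.20, permutation test).

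Genes in use in most cells and genes of tissue patterning were marked nearly throughout. All 20 cell cycle genes had a promoter peak (adjusted p = 0.0015, Fisher's exact test), with 4438 bp at Rrm2, a subunit of ribonucleotide reductase, and 4053 bp at Mki67, which encodes the proliferation antigen Ki-67. Of the 24 housekeeping genes 23 had one (95.8%, adjusted p = 0.0016, exact test), with 5533 bp at Actb and 4244 bp at Tubb5, and the remaining gene, Ywhaz, had one at another transcript. Of 24 genes of signalling in stomach development 21 had one (87.5%, adjusted p = 0.0324, exact test), with 9464 bp at Shh, the gene of the Hedgehog ligand of gut epithelium (replicates 5518.5 ± 529.6), and 8568 bp at Hes1, a Notch target (replicates 7434 ± 1656). Without merging they had 5073 and 5018 bp. Fgf10, Notch1 and Rarb had a peak only at another transcript. None of these 3 lists stood apart from random lists of equal CpG content (adjusted p = 1, 0.61 and 1, permutation test).

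**Figure D1:**
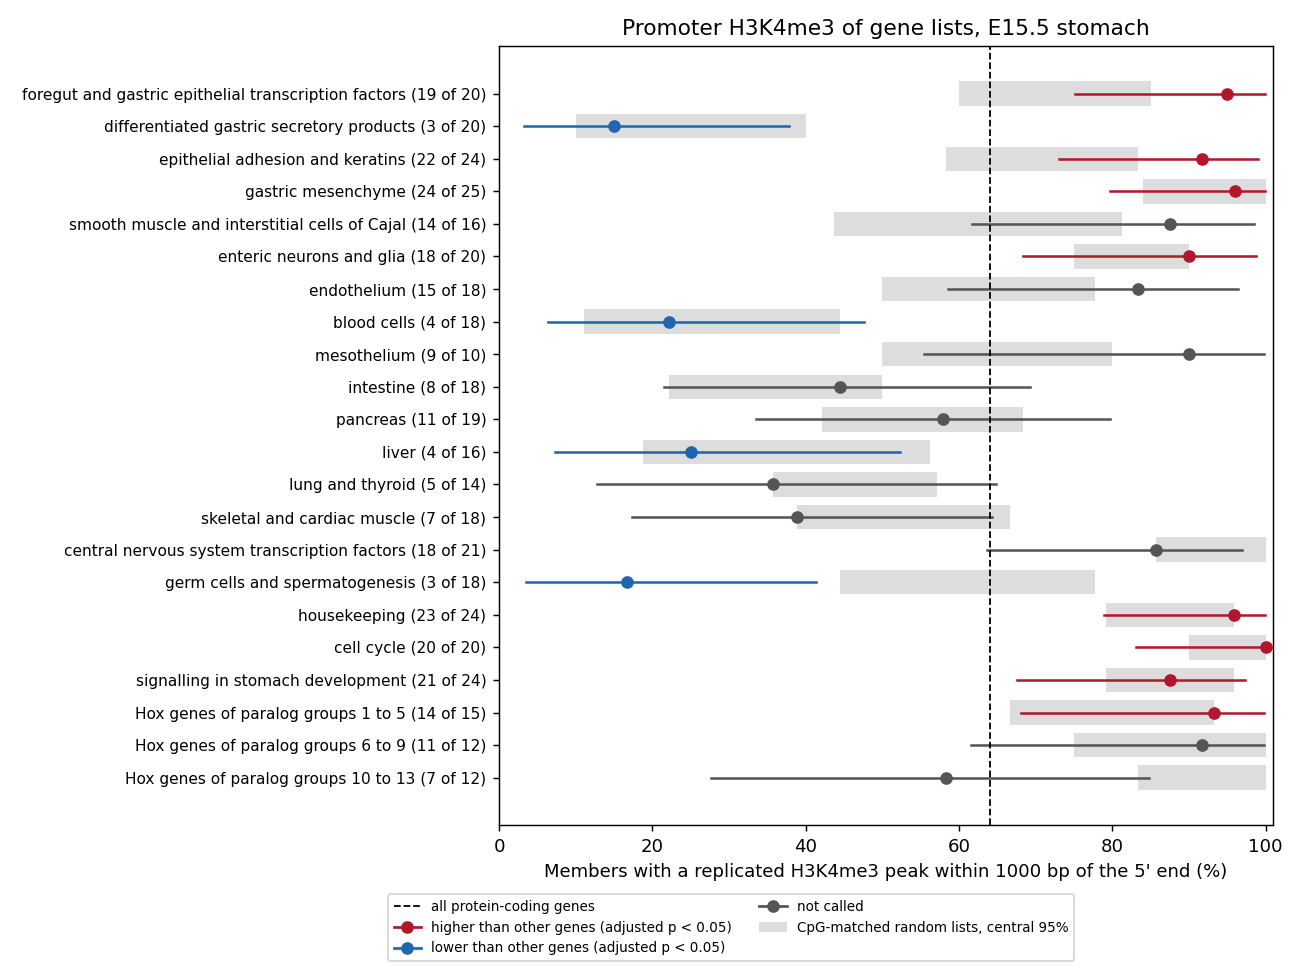
Points give the share of members (%) of each of the 22 gene lists with a replicated H3K4me3 peak within 1000 bp of the 5' end, with exact 95% intervals, and grey bars the central 95% of 10000 random lists of equal CpG content. Secretory products (15.0%) and germ cell genes (16.7%) lie farthest below the dashed line of all protein-coding genes (64.0%), and the germ cell list also lies below its grey bar.

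Promoter regions were wider than those of other marked genes in several lists, with the largest medians in gastric mesenchyme and Hox groups 1 to 5. Across 14026 genes the median width was 2134 bp, with quartiles of 1588 and 2815 bp. Of the 18 lists tested, 8 had a wider median than random lists. The medians were 6445 bp for gastric mesenchyme (24 genes), 6191.5 bp for Hox genes of paralog groups 1 to 5 (14 genes), 4925 bp for signalling in stomach development (21 genes) and 4600.0 bp for epithelial transcription factors (19 genes). They were 3961.5 bp for smooth muscle (14 genes), 3682 bp for enteric neurons and glia (18 genes), 3140.0 bp for the cell cycle (20 genes) and 2936.5 bp for epithelial adhesion (22 genes). Random lists had medians from 2123.5 to 2143.75 bp. For 6 of these lists p was 0.0002, the smallest that 10000 random lists can give (permutation test, adjusted p = 0.0006), and the adjusted permutation p was 0.0009 for the cell cycle and 0.0058 for epithelial adhesion. In the replicates' own lists the medians were 5157 ± 1513 bp for mesenchyme, 4649 ± 699 bp for epithelial factors, 4808.5 ± 308 bp for signalling and 3655.5 ± 793 bp for Hox groups 1 to 5 (SD, n = 2). The call for enteric neurons and glia was lost in each replicate's list alone, without merging of peaks and at a −log10 q of at least 10. Without merging the median fell to 3828 bp for mesenchyme and 3099 bp for Hox groups 1 to 5, against 2046.5 and 2045.5 bp for random lists, and both stayed called (adjusted permutation p = 0.0009 and 0.0022). In replicate 2 these medians were 4087 and 3095 bp.

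Narrow regions marked the posterior Hox genes and the genes of skeletal muscle and intestine. The median width was 761 bp for Hox genes of paralog groups 10 to 13 (7 genes, adjusted permutation p = 0.0009). In the replicates' own lists it was 470.0 bp over 12 genes and 360.0 bp over 7 genes. The median was 1026 bp for the intestine (8 genes, adjusted permutation p = 0.0032) and 1259 bp for skeletal and cardiac muscle (7 genes, adjusted permutation p = 0.0331). The calls for intestine and muscle were lost in replicate 2's list alone (adjusted permutation p = 0.0566 and 0.0600). Their medians there were 1210 and 1142 bp, still below random lists (1936 and 1942 bp). For the intestine the call was also lost, and the median rose, with gaps of up to 1000 bp closed (1672.5 bp), in the pooled list (1863 bp) and with all transcripts (1577.5 bp). For muscle it was lost without merging and at a −log10 q of at least 10 (adjusted permutation p = 0.0518 and 0.0571), although the median stayed at 1259 bp. Not called were the lists of endothelium (2725 bp), pancreas (2596 bp), Hox groups 6 to 9 (2433 bp), housekeeping (2430.0 bp), lung and thyroid (2283 bp), mesothelium (2041 bp) and transcription factors of the central nervous system (1780.5 bp). Secretory products, blood, liver and germ cells had too few occupied members for a test. The endothelial median turned below random lists without merging (1966 bp) and in replicate 2's list (1876 bp), but was called wider in replicate 1's list (2931 bp, adjusted permutation p = 0.0388) and against CpG-matched lists (adjusted permutation p = 0.0196). Without a call, the medians of lung and thyroid (1714 bp without merging), mesothelium (2437 bp at a −log10 q of at least 10, 2012.5 bp in replicate 2's list) and the central nervous system (2194 bp with gaps of up to 1000 bp closed) also turned. Against CpG-matched lists that of lung and thyroid turned too, and that of the central nervous system was called narrower (adjusted permutation p = 0.0126).

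**Figure D2:**
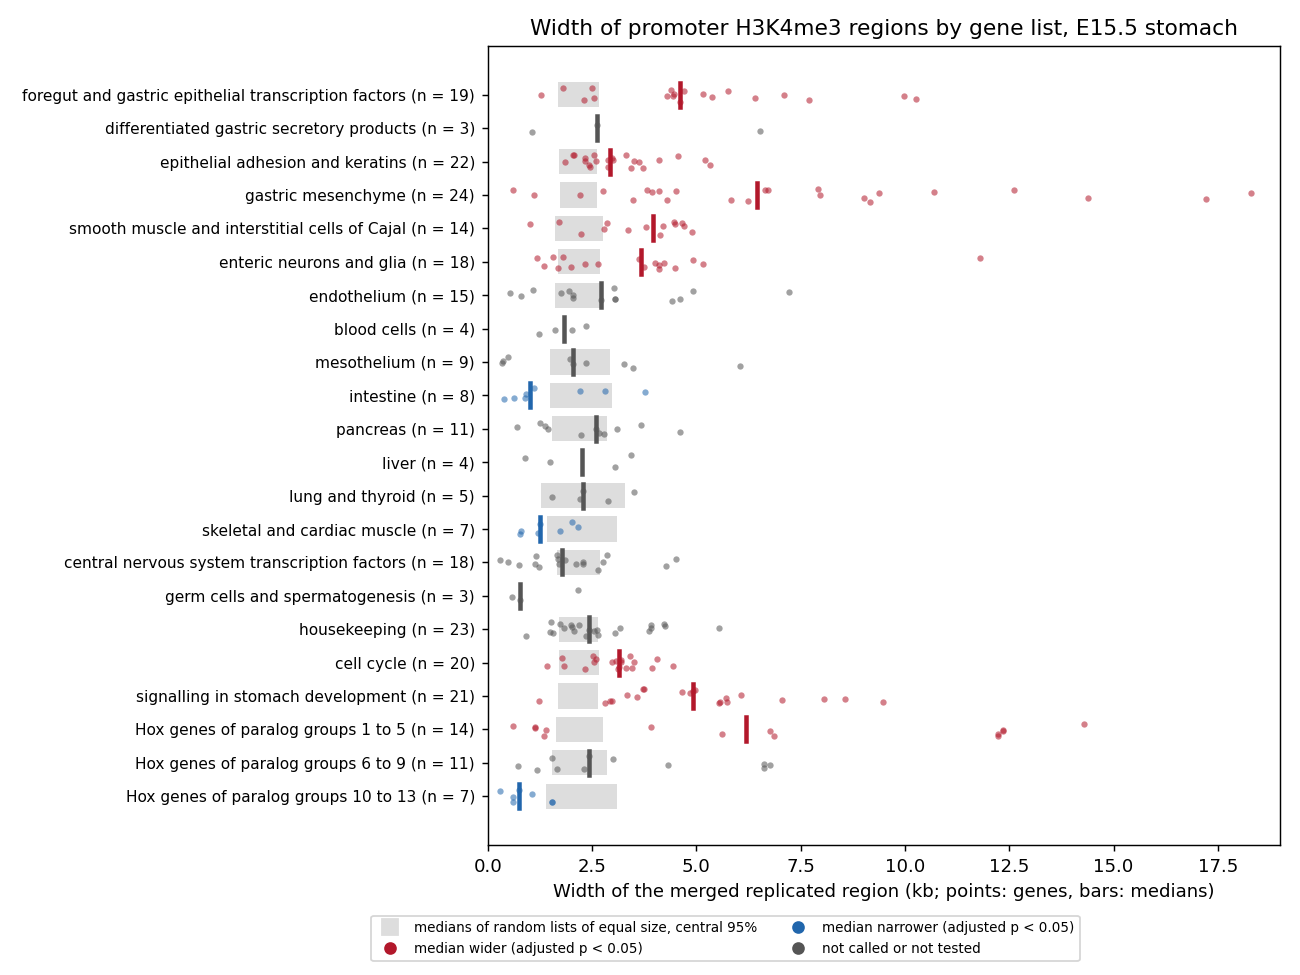
Each point is a gene with a promoter region, placed by the width of its merged replicated region (kb), with a vertical bar at the median of its list and the central 95% of medians of random lists in grey. Gastric mesenchyme reaches the widest values, with a median of 6445 bp, and Hox groups 10 to 13 stay narrow, with a median of 761 bp.

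The 10 genes with the widest promoter regions were developmental regulators and a histone demethylase gene, with 9 regions among them. After Ptch1 and Meis2 came Tbx2 (15960 bp, chromosome 11, 85829143 to 85845102), Meis1 (14386 bp, chromosome 11, 19007384 to 19021769), Hoxb5 (14290.0 bp), Pitx1 (13396 bp, chromosome 13, 55824316 to 55837711), Kdm6b (13119 bp, chromosome 11, 69407996 to 69421114), Foxf1 (12603 bp, chromosome 8, 121078621 to 121091223), and Hoxa1 and Hoxa2, which shared 12356 bp. Kdm6b encodes a demethylase of H3K27me3, and Foxf1 a forkhead factor of gut mesenchyme. The replicates gave close widths at Meis1 (14314 ± 163 bp), Kdm6b (12871.5 ± 172 bp), Pitx1 (13358 ± 277 bp) and Foxf1 (12381 ± 404 bp), and less close ones at Meis2, at Tbx2 (11950.5 ± 5662 bp), at Hoxb5 (9065.5 ± 3062 bp), at Hoxa1 (7905 ± 5609 bp) and at Hoxa2 (9208 ± 3766 bp; SD, n = 2 throughout), besides Ptch1. Without merging Tbx2 had 8487 bp, Hoxb5 7629 bp, Hoxa1 4741 bp and Hoxa2 6579 bp. In all, 19 promoter regions reached 10000 bp. At Meis1 11602 bp of the region lay inside the gene, 2868 bp of it in exons, while at Kdm6b 7439 bp lay upstream, where the region overlaps the gene Dnah2, and 5133 bp in introns. Height and width did not pick the same genes. The promoter peaks of highest enrichment were those of Prrc2a (68.03-fold, 4124 bp), C1qbp (67.2-fold, 2089 bp), Wtap (67.17-fold, 2879 bp), Snu13 (67.17-fold, 2441 bp) and Dctn2 (67.1-fold, 1854 bp), whereas Ptch1 had 50.3-fold, Meis2 37.3-fold and Tbx2 30.3-fold as the highest value in the region.

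**Figure D3:**
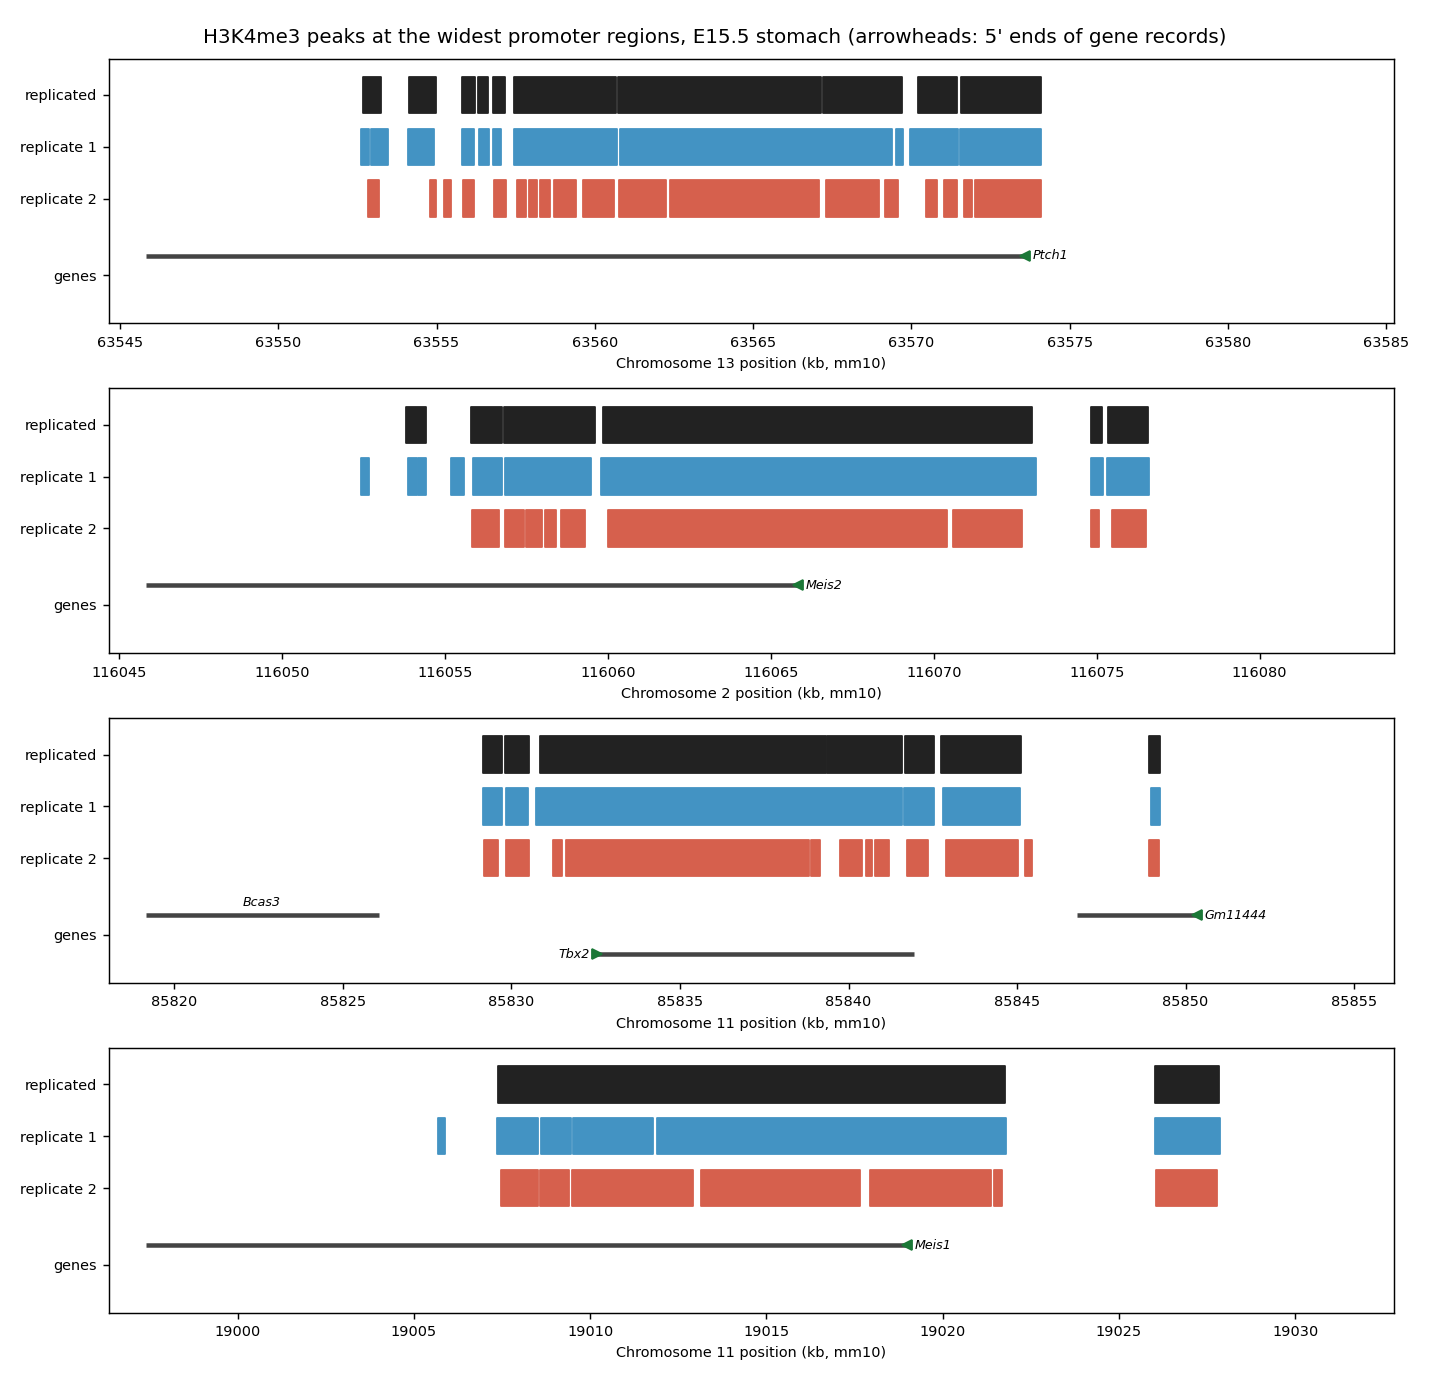
Peaks of the replicated list and of each replicate (bars) are drawn along chromosome position (kb) with gene records below, around the 4 widest promoter regions, at Ptch1, Meis2, Tbx2 and Meis1. The region of Ptch1 is nearly continuous in replicate 1 (18271 bp at the promoter) and divided by gaps in replicate 2 (3627 bp), while Meis1 is 14429 bp and 14199 bp wide.

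Over the Hoxa and Hoxb clusters, which encode homeobox factors of position along the body axis, H3K4me3 was broad at most anterior genes and narrow or missing at the posterior ones. A promoter peak lay at 14 of 15 genes of paralog groups 1 to 5 (93.3%, adjusted p = 0.0324, Fisher's exact test), 11 of 12 of groups 6 to 9 (91.7%, adjusted p = 0.0866) and 7 of 12 of groups 10 to 13 (58.3%, adjusted p = 0.77, exact test for both). By cluster, 9 of 11 Hoxa genes on chromosome 6, all 10 Hoxb genes on chromosome 11, 6 of 9 Hoxc genes on chromosome 15 and 7 of 9 Hoxd genes on chromosome 2 had one. In the Hoxa cluster regions of 12356 bp (Hoxa1 and Hoxa2), 6871 bp (Hoxa5) and 6770.0 bp (Hoxa3 and Hoxa6) gave way to 2311 bp at Hoxa7. Hoxa4 had 3905 bp. The gene record of Hoxa3 starts beyond Hoxa6, so its 6770.0 bp do not lie at the anterior end of the cluster. Replicate 2 alone had 3939 bp at Hoxa1, 6545 bp at Hoxa2, 6179 bp at Hoxa5, 3116 bp at Hoxa3 and 2882 bp at Hoxa6, against 1862 bp at Hoxa7. Without merging Hoxa3 had 3124 bp and Hoxa6 2347 bp, close to Hoxa7. With gaps of up to 1000 bp closed Hoxa1 and Hoxa2 had 24798 bp and Hoxa3, Hoxa5 and Hoxa6 14205 bp, the latter also in the pooled list. Hoxa9 and Hoxa10 had no peak at the 5' end of the gene record but had one at another transcript. Hoxa11 had 613 bp (515 bp in replicate 1 and 360 bp in replicate 2) and Hoxa13 1534 bp. Hoxb1, the most anterior gene of its cluster, was an exception with 1354 bp and 5.33-fold. In the Hoxb cluster widths were otherwise 12227 bp at Hoxb3 and Hoxb4, 14290.0 bp at Hoxb5 and 4322 bp at Hoxb6. Further widths were 6627 bp at Hoxb7 and Hoxb8, 1669 bp at Hoxb9 and 761 bp at Hoxb13. In replicate 2 they were 7408 bp at Hoxb3, 3394 bp at Hoxb4, 6900.0 bp at Hoxb5, 5567 bp at Hoxb7 and Hoxb8, 1614 bp at Hoxb9 and 338 bp at Hoxb13, with 422 bp at Hoxb2 in place of 5613 bp. Without merging Hoxb3 had 3074 bp, Hoxb4 3939 bp and Hoxb2 2929 bp. At the 5' ends of gene records the Hoxc and Hoxd clusters had no region as wide: the widest were 2994 bp at Hoxc6 and 2433 bp at Hoxd8, and Hoxc13 had 1551 bp. The anterior Hoxd1 had 1394 bp, and Hoxd3 and Hoxd4 shared 1142 bp, no wider than Hoxc13. With all transcripts Hoxc5 had 3425 bp, Hoxc6 3334 bp, Hoxd3 2171 bp and Hoxd4 1856 bp. Hoxc11, Hoxc12 and Hoxd12 had no replicated peak at any transcript, and Hoxc4 and Hoxd11 had one only away from the gene record's 5' end. Replicate 1 alone had a promoter peak at all 12 genes of groups 10 to 13, replicate 2 at 7 and the pooled list at 11, so the missing peaks of the other genes rested on replicate 2 and the replicated list. In replicate 1's list the group was called higher than other genes (100%, adjusted p = 0.0207, Fisher's exact test). The share also turned above that of other genes with windows of 2500 bp (11 of 12, 91.7%) and with all transcripts (9 of 12, 75%), without a call. Against random lists of equal CpG content, with a median of 100%, the 58.3% of groups 10 to 13 was lower (adjusted p = 0.0022, permutation test). The call for groups 1 to 5 was lost among such lists (adjusted p = 0.16, permutation test) and at a −log10 q of at least 10 (13 of 15, adjusted p = 0.0853, exact test). Several gene records share a region or start at a neighbour's promoter, so the values of neighbours are not independent. An example is Hoxc5 and Hoxc10 (620.0 bp, but 1432 bp in replicate 1 and 209 bp in replicate 2).

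**Figure D4:**
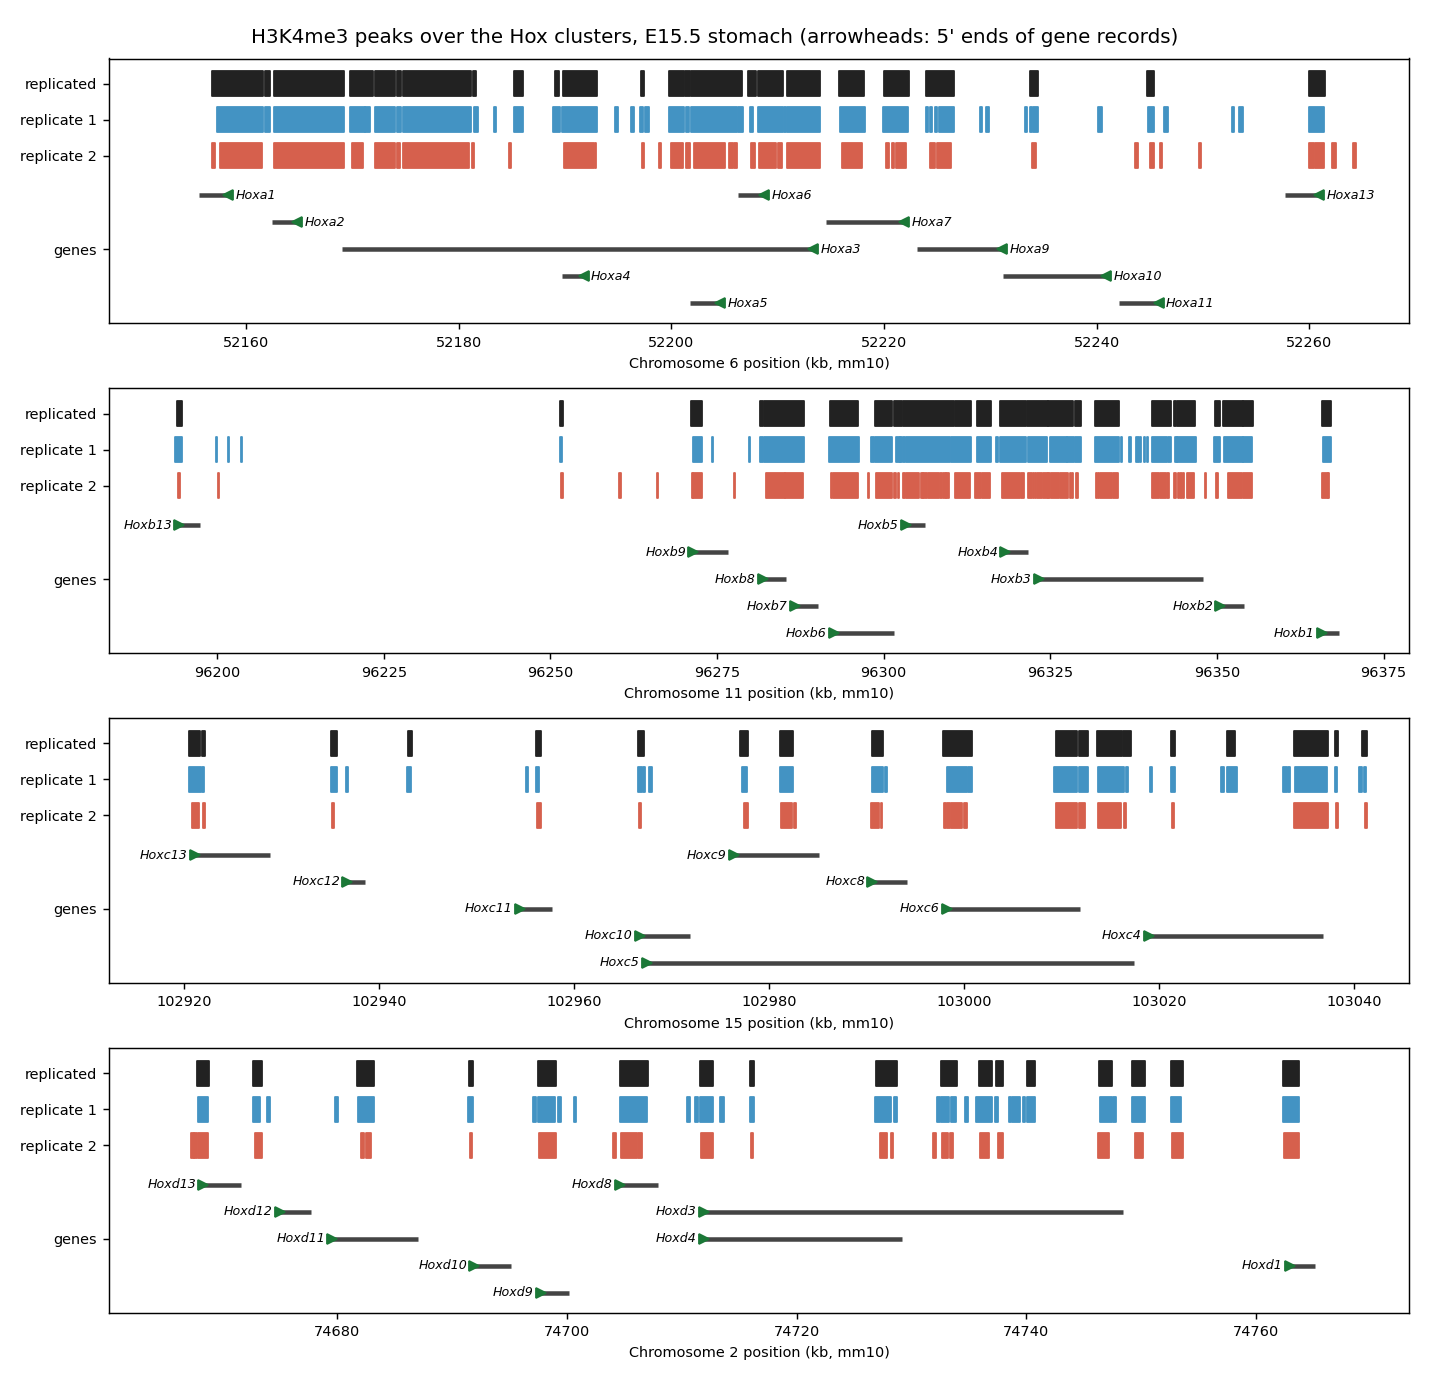
Replicated peaks and the peaks of each replicate (bars) are drawn along position (kb) for the Hoxa, Hoxb, Hoxc and Hoxd clusters, with gene records below and arrowheads at their 5' ends. Marked stretches are densest at Hoxa1 to Hoxa7 and Hoxb2 to Hoxb8, and isolated narrow peaks lie at Hoxb13 (761 bp) and Hoxa11 (613 bp).

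Away from annotated 5' ends the mark was weaker, with some exceptions as strong as promoters. There were 2594 replicated peaks (10.8%) more than 10000 bp from any 5' end of any gene or transcript, with a median width of 604.5 bp and a median enrichment of 5.15-fold, and 579 of them reached 10-fold. The highest enrichments were 52.4-fold on chromosome 12 from 8640208 to 8641769, between genes and 33183 bp from the 5' end of Pum2, and 51.5-fold on chromosome 9 from 67631816 to 67634738, between genes with Tln2 the nearest protein-coding gene, 74207 bp away. The next were 51.2-fold on chromosome 15 from 85669574 to 85673361, in an intron of the long noncoding RNA gene Lncppara, and 48.3-fold on chromosome 11 from 74637327 to 74639398, in an exon of Ccdc92b and 11019 bp from the 5' end of Cluh. The last was 46.3-fold on chromosome 9 from 32031571 to 32034200, between genes. It lay 11960 bp from the 5' end of the processed pseudogene Gm47481 and 83238 bp from that of Arhgap32, the nearest protein-coding gene. Each of these 5 peaks overlapped a peak in both replicates.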

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

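In data that entered no gene or position comparison, 11 replicated peaks lay on scaffolds outside the assembled chromosomes. The strongest, on a scaffold assigned to chromosome 4, was 2060 bp wide with an enrichment of 30.0-fold, and no gene annotation was used there. Each replicate's own list held such peaks too, 12 in replicate 1 and 19 in replicate 2. Among the tests below, counting each region once was chosen after the widths had been seen.

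Wide promoter regions of gene lists were weighed against technical explanations. Against the CpG content of the promoters, 8 of the 8 wide lists stayed wider than random lists of equal CpG decile. The decile covers only the 1000 bp on each side of the 5' end. CpG content farther along the wide regions was not matched, so its part in the width remains open. Against regions counted for several neighbouring genes, 8 of 8 stayed wider with each region counted once, and against peak calls of 1 replicate, at least 7 of 8 did in either replicate's own list, the exception being enteric neurons and glia. With no gaps closed 7 of 8 stayed wider, and the call for enteric neurons and glia ended because its median fell from 3682 bp (random lists 1678 to 2684) to 2271 bp (random lists 1620 to 2557). The joining of peaks by the caller and the unknown depth remain open, and the design holds no other tissue or stage, so no biological explanation was tested.

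For gene lists with few promoter peaks, CpG content of the promoters may account for most of the pattern, since 1 of the 4 low lists stayed lower than random lists of equal CpG decile. Secretory products had 15.0% against a matched median of 25% (central 95% 10 to 40), blood 22.2% against 27.8% (11.1 to 44.4) and liver 25% against 37.5% (18.75 to 56.25). These calls ended because the reference fell from 64.0%, while germ cell genes, at 16.7% against 61.1% (44.4 to 77.8), stayed lower. The 5' ends of the gene records do little to account for it, since 5.17% of the 58 members without a peak gained one at another transcript. Over the 4 lists together, peaks lost to the replication requirement do little too, since 10.3% had a peak in another list. Blood was an exception, with a peak at 9 of 18 members in the pooled list against 4 of 18 in the replicated list. It was no longer called in the pooled list, so for blood the replication requirement remains open. No biological explanation was tested.

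Peaks called in 1 replicate only were mostly weak calls near the threshold. Their median rank by −log10 q within the own list was at percentile 16.7 in replicate 1 and 14.0 in replicate 2, below the bound of 25 set beforehand. Whether they are fragments beside a peak of the other replicate stays open, since 50.7% in replicate 1 and 38.1% in replicate 2 lay within 1000 bp of one, between the bounds of 25% and 75% set beforehand. A difference in depth could not be examined, and no biological explanation was tested.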

How the results depend on the processing

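Alternatives added after the data were seen were the widths with each region counted once and with all transcripts' 5' ends, and the position classes in the pooled list. The overlap of the replicates stayed above random placement under each alternative (65.5% to 99.5% of replicate 1's peaks and 65.3% to 100% of replicate 2's), and the odds ratio for lying at a 5' end kept its direction and its side of the threshold. The replicated share of pooled peaks was 99.9% at a −log10 q of at least 10, as weak peaks drop out, and the reciprocal overlap left it as it was because replicated peaks are copies of pooled ones. Promoter occupancy, 64.0%, was 63.0% and 65.6% with windows of 500 and 2500 bp, 67.6% with all transcripts, 62.3% at a −log10 q of at least 10, 65.4% in the pooled list and 64.2% to 64.9% without either replicate. The share of peaks at 5' ends, 57.6%, was 61.3% by any overlap, 66.3% at a −log10 q of at least 10, 46.0% in the pooled list and 47.3% to 48.6% without either replicate, where peaks that did not replicate are counted.

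The number of lists called for occupancy, 12, was 4 among CpG-matched random lists, 3 of them called in the main comparison, and 12 to 16 otherwise. For Hox groups 10 to 13 the share was 58.3% without replicate 1 and the direction was reversed without replicate 2, at 100% (adjusted p = 0.0207, Fisher's exact test), and the cause was not tested. Of the other alternatives for single lists 145 kept their side of the threshold, 17 passed it and 13 missed it. For widths, 8 to 13 lists were called in place of 11, and 147 alternatives for single lists kept their side of the threshold, 3 passed the threshold and 11 missed it. The width of named promoter regions moved by more than the spread between replicates in 144 alternatives and by less in 453. Lists of 10 to 25 genes, with as few as 5 occupied members in the width tests, limit what these tests can detect. The unknown depth limits any reading of an absent peak as an absent mark. No paired analysis was possible because there was 1 group.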

Other observations

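Olfactory receptor genes, a family used in sensory neurons of the nose, carried almost no H3K4me3 in the stomach. A promoter peak lay at 3 of 1134 genes (0.265%, exact 95% interval 0.0546 to 0.771), and the class was chosen after the data were seen. Their promoters are poor in CpG, with a median observed to expected ratio of 0.109 against 0.498 for other protein-coding genes. On chromosome Y, present in these pools of both sexes, the replicated list had 6 peaks. They were nearest to Eif2s3y (2 peaks), Uty, Ddx3y, Kdm5d and Uba1y, genes with relatives on chromosome X, with enrichments from 4.32 to 12.1-fold.

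Most lists with wide regions did not have high ones, and the same held for most of the lists tested. For each gene the highest enrichment in its promoter region was set against random lists of equal CpG decile, a measure chosen after the data were seen. Of 18 lists 13 had a lower median, 1 a higher one (housekeeping, 50.7 against 41.1-fold, adjusted p = 0.0067, permutation test) and 4 were not called. Of the 8 lists with wide regions 6 were among the lower ones, such as gastric mesenchyme (30.0 against 43.0-fold, adjusted permutation p = 0.0048) and enteric neurons and glia (17.2 against 40.9-fold, adjusted permutation p = 0.0009). Smooth muscle (17.8 against 28.1-fold) and the cell cycle (44.8 against 42.4-fold) were not called (adjusted permutation p = 0.17 and 0.46). Lists without wide regions were lower too, such as Hox groups 10 to 13 (4.99 against 43.8-fold, adjusted permutation p = 0.0009). Low enrichment was therefore not particular to wide regions. The values are the authors' enrichments in the replicated list.

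Narrow promoter regions at transcription factor genes of the central nervous system were tested with a hypothesis formed after the unmatched widths had been seen, that they are narrower than promoters of equal CpG content. The median of the 18 occupied genes was 1780.5 bp against 2318 bp in CpG-matched random lists (central 95% 1917 to 2799.5), with a permutation p of 0.0070 (adjusted p = 0.0126). Against random lists not matched on CpG the permutation p was 0.14 (adjusted p = 0.20). With gaps of up to 1000 bp closed the median turned above such lists (2194 against 2164.5 bp, permutation p = 0.91). In the other unmatched alternatives it lay below them without a call. The CpG-matched test was run only with gaps of up to 500 bp closed, so the narrower width is shown for that merging only. The highest enrichment in these regions was also lower, with a median of 10.3 against 43.6-fold (adjusted permutation p = 0.0009). Such promoters may carry a mark in part of the cells or at a low level, which bulk peak lists of 1 tissue cannot separate.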
